A study of Drosophila melanogaster with 16 samples.

How the data were processed

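Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map protein-bound DNA in S2 cells, a cultured Drosophila melanogaster line of embryonic origin. The series comprised 16 libraries from 3 genotypes: unmodified cells (WT), cells with induced dBigH1 and cells with induced dBigH1ΔED, a form whose abbreviation the labels do not spell out. Every sample was treated with 1 mM copper sulphate for 24 h, WT included. Rpb3, a subunit of RNA polymerase II, was immunoprecipitated in all 3 genotypes, with 2 libraries each. The linker histone H1 and the protein recognised by the dBigH1 antibody were immunoprecipitated in dBigH1ΔED cells alone, again with 2 libraries each. The remaining 6 libraries were inputs, which came with no peak list and were not analysed here. The labels' protocol describes polyclonal antibodies against dBigH1 and H1, while the Rpb3 antibody was taken from the per-sample labels.

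The authors deposited 1 peak list per immunoprecipitated library, 10 in all, so peaks had been called in each replicate separately. FastQC version 011, Bowtie version 0.12.5, MACS version 1.4.2 and genome build dm3 are named, with no order or settings, per the submitters' processing notes. Each deposited list gave a position and a score for every peak, and the lowest score in any list was 50.0. What the score measures was not given in the sources used here. Scores piled up at or just above 3100 in the Rpb3 lists. The scores are the authors' own and were used to describe each list and to rank or filter peaks within it, with no test of scores between lists. Whether inputs served as controls, how reads were filtered and how many reads each library held were not given in the sources used here. The depth behind each list was therefore unknown, and a peak missing from a list was treated as not called, not as absent binding. Nothing said that replicates came from separate cultures, so p-values from permuting libraries measure only the spread between these libraries, which may be technical. P-values from shifted positions, from counts of regions and from bins of the genome do not use that spread.

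Positions were converted to 1-based dm3 coordinates. The reference at hand was a gene table of another assembly, Release 6. Its coordinates were not used, regions are given by position alone, and the gene lists planned at transcription start sites were not analysed here.

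Peaks sharing at least 1 bp were joined across lists into regions, and a region counted as specific to a genotype when both of its libraries and neither library of the other held it. The 4 libraries of a comparison can be split into pairs in 3 ways, so the genotype count was set beside the counts from the other splits. Peak number, covered length and chromosome shares were compared by two-sided exact permutation tests, which cannot go below p = 0.333 with 2 libraries against 2. Similarity between lists was the Jaccard index, the bases shared by both lists divided by the bases in either. Its mean within and between genotypes was compared over the 15 ways of pairing 6 libraries, with 0.0667 the smallest possible p. Overlap between antibodies was tested on reproducible regions, those held by both libraries, against 10000 circular shifts along each chromosome, two-sided, where 0.0002 is the smallest p. Benjamini-Hochberg adjustment covered the 21 overlap tests. Chromosome spans were taken as the furthest peak end in any list. Intervals for shares are exact Clopper-Pearson 95% intervals and cover counting error only.

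Named regions followed a rule fixed before the data were examined. It took the 10 genotype-specific regions per direction and comparison whose poorer rank within the 2 lists was best, and the 5 best-ranked and 5 widest reproducible regions per antibody and genotype. Examples were drawn from those lists, and exceptions are stated. Alternatives were a score of at least 100, the 5 large chromosome arms alone, equal numbers of best-scored peaks, an overlap of 50% of the shorter peak, joining of peaks within 500 bp, random placement in place of shifts, each replicate left out, and a replicate block.

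Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. The calls were tested on simulated data of 1200 regions for dBigH1 against WT, with 200 regions lost, 100 gained and 3% of peaks dropped from each list at random. The procedure recovered 95.5% of the lost and 94% of the gained regions, with 2 false calls. Peaks were dropped there regardless of score, so these figures do not give the rate of false calls in the real lists. In 100 simulated overlap tests, 3 randomly placed sets and 100 sets kept apart fell below 0.05.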

Results

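The data comprised peak lists from 10 ChIP-seq libraries of S2 cells. RNA polymerase II was followed through its subunit Rpb3 in WT cells, in cells with induced dBigH1, the linker histone of the early Drosophila embryo, and in cells with induced dBigH1ΔED. Linker histones bind DNA where it enters and leaves the nucleosome, and H1 is the form found in somatic cells. H1 and the protein recognised by the dBigH1 antibody were mapped in the dBigH1ΔED cells. The series title places the study in the question of how dBigH1 affects active chromatin, which the Rpb3 comparisons address. Each group had 2 libraries, and all errors below are SD with n = 2 unless another n is given. Read depth was unknown.

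Rpb3 lists held between 4655 and 4933 peaks, and the number of peaks did not separate the genotypes. WT libraries had 4781 ± 80.6 peaks, dBigH1 libraries 4794 ± 197 and dBigH1ΔED libraries 4736 ± 33.9. Sequence under Rpb3 peaks was shortest in dBigH1ΔED cells, at 16.0 ± 0.198 Mb, against 17.2 ± 0.326 Mb in dBigH1 cells and 17.8 ± 1.33 Mb in WT cells. Both dBigH1ΔED libraries lay below all 4 others. Rpb3 peaks were spread over all large arms, and chromosome X held 20.3 ± 0.254% of them in WT, 19.8 ± 0.279% in dBigH1 and 19.4 ± 0.154% in dBigH1ΔED cells. The best-ranked reproducible WT region lay on chromosome 2R from 17265676 to 17267726, and the widest, of 30978 bp, on 2R from 19906252 to 19937229. In dBigH1 cells the best-ranked region lay on 2L from 19050932 to 19055420, and in dBigH1ΔED cells on 2R from 14326910 to 14329593. The widest dBigH1ΔED region spanned 38287 bp of X from 16308517 to 16346803.

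**Figure D1:**
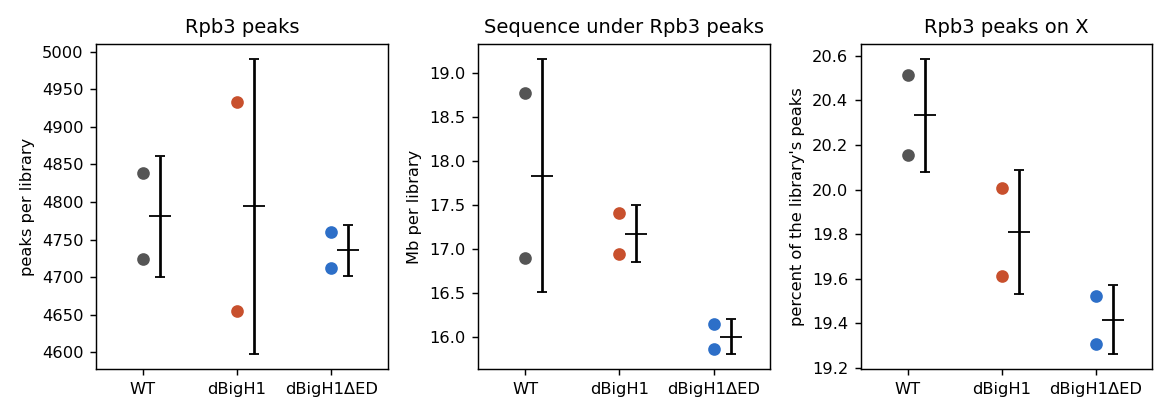
Peaks per Rpb3 library, megabases of sequence under those peaks, and percent of peaks on chromosome X for the 3 genotypes (axes do not start at 0). Points are single libraries and bars are mean ± SD with n = 2; the dBigH1ΔED libraries covered 16.1 and 15.9 Mb, below all 4 other libraries.

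Most Rpb3 regions were shared by WT cells and cells with induced dBigH1. No uninduced library of either induced line was included, so cell line and induced protein coincide in every comparison. Of 4997 regions in the WT and dBigH1 lists, 3942 (78.9%) were held by all 4 libraries, 163 by both WT libraries alone and 91 by both dBigH1 libraries alone. Among the regions missing in dBigH1 cells were 2R 8866394 to 8869375 and X 5784724 to 5799883, which scored 3100 in both WT libraries, and X 14612197 to 14617139. Regions called in dBigH1 but not WT cells included 3L 20516838 to 20535470, at score 3100 in both dBigH1 libraries, 2L 2172349 to 2181783 and 3R 11617666 to 11630947. The heterochromatic scaffold 3LHet held 6 regions specific to dBigH1, 0 specific to WT and 10 of those common to all 4 libraries, with no test run. Some of the 6 were near neighbours, such as 1718100 to 1719840 and 1719882 to 1725273. Most regions specific to a genotype were weak, and those specific to WT were also narrow. Their median width was 1721 bp for WT and 2372 bp for dBigH1. All reproducible regions had medians of 2809.5 bp in WT and 2593 bp in dBigH1 cells. The 3028 bp of regions in all 4 libraries is a less like comparison, since joining more lists widens regions. For regions specific to WT and to dBigH1, the median rank in the poorer list lay 91.5% and 87.9% of the way down. In the better-ranked 50% of both lists the balance was the other way, with 10 regions specific to WT and 15 to dBigH1.

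The genotype split gave 254 regions, against 64 for the split by replicate number and 46 for the crossed split (exact permutation p = 0.333, the smallest possible). Covered length differed by -0.659 Mb, within the spread of the libraries (exact permutation p = 1), and by 0.280 Mb in the other direction without WT replicate 1. Leaving out 1 library loosens the definition of a specific region. The count was then 405 without dBigH1 replicate 1, 418 without dBigH1 replicate 2, 435 without WT replicate 1 and 528 without WT replicate 2. WT held more of them each time, but the balance moved. It was 217 against 201 without dBigH1 replicate 2 and 354 against 174 without WT replicate 2.

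Cells with dBigH1ΔED differed from WT cells at more Rpb3 regions, with more of them missing than gained. Of 5072 regions, 3808 (75.1%) were held by all 4 libraries, 279 by both WT libraries alone and 139 by both dBigH1ΔED libraries alone. Missing regions included X 5784724 to 5799883, which was also missing in dBigH1 cells, 2R 3801664 to 3810436 and 3R 17135503 to 17147406. Gained regions included 3R 10520433 to 10524246, 3L 5742160 to 5749605 and 3R 11796910 to 11802782, with scores of at least 3100 in both dBigH1ΔED libraries. Chromosome X held 77 of the 279 missing and 22 of the 139 gained regions. The scaffold 3LHet held 5 gained and 0 missing regions, and 10 of those common to all 4 libraries. Regions specific to WT had a median width of 1647 bp and a median poorer rank 91.7% of the way down the list. The excess of missing regions came from weak peaks: in the better-ranked 50% of both lists, 5 regions were missing and 25 gained.

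The genotype split gave 418 regions, against 49 and 43 for the other splits (exact permutation p = 0.333, the smallest possible), and 727 without WT replicate 2. Covered length differed by -1.83 Mb (exact permutation p = 0.333), which was -0.893 Mb without WT replicate 1 and -2.77 Mb without WT replicate 2. Both dBigH1ΔED lists also had lower scores as a whole, with medians of 639 and 692 against 822 to 961 in the other 4 Rpb3 lists, and 448 and 459 peaks at 3100 or above against 595 to 732. Depth was unknown, so neither the missing regions nor the shorter covered length can be separated from a difference in sequencing.

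**Figure D2:**
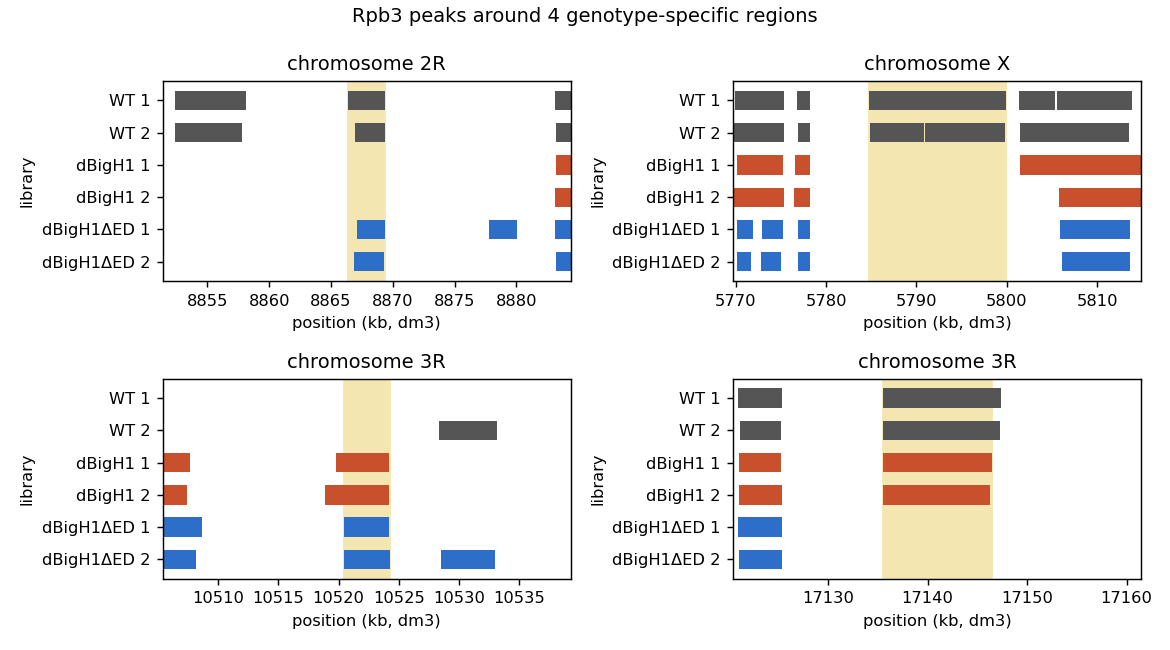
Rpb3 peaks (bars) in the 6 libraries, by position in kb of dm3, around 4 named regions (shaded). The 2R region was called in WT and dBigH1ΔED but not dBigH1 libraries, the X region in WT libraries alone, the left 3R region in both induced lines but not WT, and the right 3R region in WT and dBigH1 but not dBigH1ΔED libraries.

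The Rpb3 peak lists of the dBigH1 and dBigH1ΔED lines also differed when set against each other. Of 5050 regions, 3899 (77.2%) were held by all 4 libraries, 240 by both dBigH1 libraries alone and 137 by both dBigH1ΔED libraries alone. Regions called with dBigH1 and not with dBigH1ΔED included 2R 19906578 to 19917922, 3R 17135505 to 17146461 and 2L 2172349 to 2181783. The first lies within the widest WT region, 2R 19906252 to 19937229, which was not specific to WT against dBigH1ΔED. A dBigH1ΔED peak therefore overlapped that WT region, and the call depends on how the stretch was divided into peaks. Regions called with dBigH1ΔED and not with dBigH1 included 2R 8866881 to 8869325, 3L 5742160 to 5749605 and 2L 2181977 to 2184808. The last of these adjoins the dBigH1-specific 2L region, under 500 bp away. Joining peaks within 500 bp makes them a region common to all 4 libraries, so this site is not specific under that setting. Chromosome X held 65 of the 240 regions specific to dBigH1 and 16 of the 137 specific to dBigH1ΔED. In the better-ranked 50% of both lists, 16 regions were specific to dBigH1 and 21 to dBigH1ΔED.

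The genotype split gave 377 regions, against 43 and 54 for the other splits (exact permutation p = 0.333, the smallest possible), with 602 without dBigH1 replicate 2 and 580 without dBigH1ΔED replicate 2. Covered length was 1.17 Mb greater with dBigH1 (exact permutation p = 0.333). The lower scores of the dBigH1ΔED lists and the unknown depth limit this comparison as they do that with WT.

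**Figure D3:**
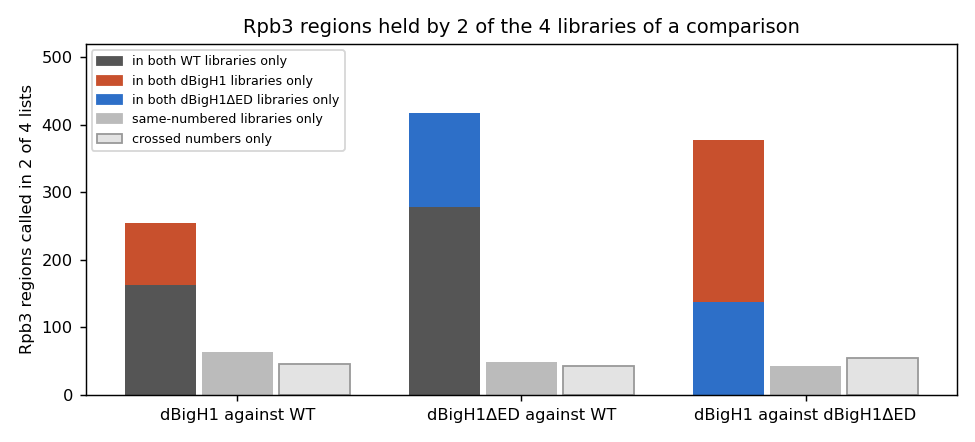
Number of Rpb3 regions called in exactly 2 of the 4 libraries of each comparison, by which 2 libraries held them. Coloured bars are the genotype split, stacked by genotype (254, 418 and 377 regions); grey bars are the splits by replicate number (64, 49 and 43) and across numbers (46, 43 and 54).

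Libraries of 1 genotype resembled each other more than libraries of different genotypes. The Jaccard index averaged 0.819 ± 0.0235 within genotypes (n = 3 pairs, 0.792 to 0.835) and 0.745 ± 0.0248 between them (n = 12 pairs, 0.703 to 0.786), so every pair within a genotype exceeded every pair between genotypes (exact permutation p = 0.0667, the smallest possible). Between genotypes it was 0.769 ± 0.0181 for dBigH1 and WT, 0.741 ± 0.00101 for dBigH1 and dBigH1ΔED, and 0.725 ± 0.0244 for dBigH1ΔED and WT (n = 4 pairs each). Over all 6 lists, 3656 of 5097 regions (71.7%) were common to every library. Both WT libraries alone held 95 regions, and both induced lines but not WT held 32, among them 3R 10518893 to 10524246 and 2R 2388690 to 2390339. The 95 regions lost in both lines compare with 8.34 for independent lists. They compare with 21.3 (13 to 30) when the calls of all 6 libraries were shuffled within each region. The 32 gained in both compare with 2.31 and 19.4 (12 to 28). The WT libraries were too few to be split, so part of either excess may come from the shared controls. Shuffling also removes any difference that runs through a whole library, so its values may be too low.

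Called H1 peaks seldom overlapped called Rpb3 peaks in dBigH1ΔED cells. The H1 lists held 1917 and 1846 peaks, of which 812 regions were reproducible, with a Jaccard index of 0.254. Of these, 21 (2.59%, interval 1.61 to 3.93%) overlapped a reproducible Rpb3 region of the same cells, against 165 (136 to 193) after circular shifts (permutation p = 0.0002, the smallest possible, adjusted p = 0.00028). With the 1846 best-scored peaks of every list, 4 of 795 (0.503%) overlapped, against 9.26% after shifts, at the same permutation p. On the arms, the median distance from an H1 region to the nearest Rpb3 region was 27475 bp, against 8069 bp (5858 to 11106) after shifts (permutation p = 0.002, the smallest possible). The best-ranked H1 regions were 3RHet 417707 to 423903, 3L 17273826 to 17279551 and 3L 3016303 to 3022667, and the widest spanned 15794 bp of 2L from 16206815 to 16222608. Heterochromatic scaffolds held 10.9 ± 2.00% of H1 peaks, against 1.18 ± 0.00847% of Rpb3 peaks in the same cells. Chromosome X held 20 and 19 H1 peaks, 1.04 ± 0.00993%, and chromosome 4 held 0 in either list. At the density of the 4 autosomal arms, X would have held 364 and 368, and chromosome 4 would have held 20.4 and 20.7. Because H1 peaks lay in megabase blocks, described below, shifts along whole chromosomes cannot separate avoidance of single sites from separate blocks. H1 was mapped in these cells only, so its placement without dBigH1ΔED was not analysed here.

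**Figure D4:**
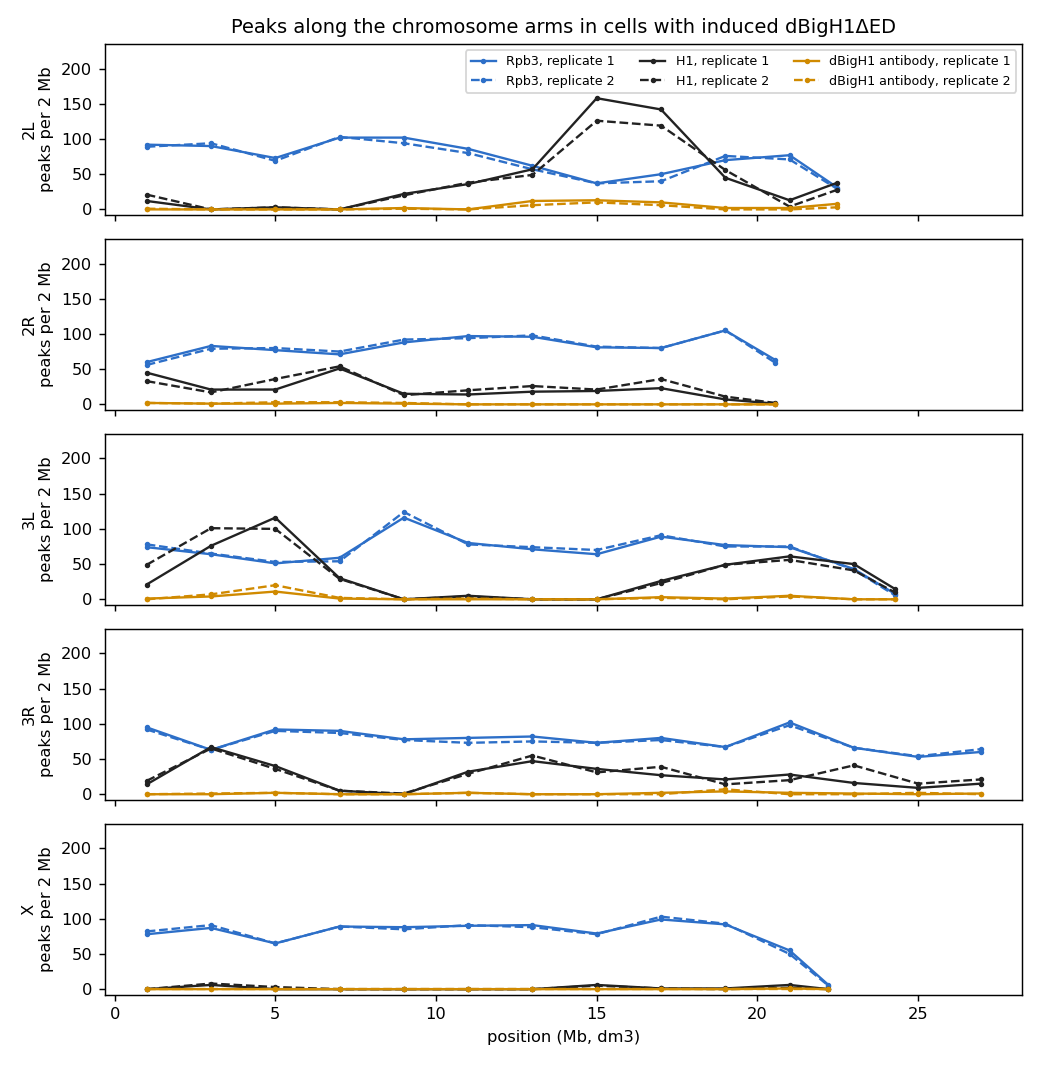
Peaks per 2 Mb window along the 5 large arms in dBigH1ΔED cells (last window of an arm shorter), by position in Mb of dm3; solid and dashed lines are replicates 1 and 2. H1 peaks numbered 300 and 245 between 14 and 18 Mb of 2L, an interval chosen after the peaks were seen, where Rpb3 peaks numbered 87 and 77, and X held 20 and 19 H1 peaks in all.

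The dBigH1 antibody gave few peaks in dBigH1ΔED cells, and few of them repeated. The lists held 119 and 96 peaks, with 7 reproducible regions and a Jaccard index of 0.0237. These were 2L 14169854 to 14174645, 2L 14966256 to 14971017, 2R 1395479 to 1397269, 3L 5030543 to 5034127, 3L 20874617 to 20879762, 3L 21408355 to 21412404 and 3LHet 721696 to 728141, all given here although the 2R region fell outside the naming rule. No reproducible region overlapped Rpb3 (0 of 7, against 1.49 after shifts, permutation p = 0.375) and 2 of 7 overlapped reproducible H1 regions (against 0.545, permutation p = 0.203), so neither differed from shifted positions at this number. Against a single H1 list the overlap was 5 of 7 without H1 replicate 2 (permutation p = 0.003) and 3 of 7 without H1 replicate 1 (permutation p = 0.105), so the call rests on which list is used. With the 96 best-scored peaks of every list, 0 of 7 overlapped either Rpb3 or H1. Shifts then gave only 0.876% and 0.153%, so 0 was the likely outcome in any case and this setting decides nothing.

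Taken library by library, peaks of the dBigH1 antibody overlapped Rpb3 less often and H1 more often than shifted positions. Reproducible Rpb3 and H1 regions were the reference. In replicate 1, 7 of 119 peaks overlapped Rpb3, against 23.5 after shifts, and in replicate 2, 2 of 96, against 21.1 (permutation p = 0.0002 for each, the smallest possible). Overlap with H1 was 25 of 119, against 7.45 (permutation p = 0.0004), and 32 of 96, against 5.80 (permutation p = 0.0002). Against single H1 lists the shares were higher and uneven: 63.9% and 51.0% of the peaks in replicates 1 and 2 overlapped H1 replicate 1, and 25.2% and 41.7% overlapped H1 replicate 2, with no test run. The adjusted p of the 4 tests ranged from 0.00028 to 0.000494. Each test describes 1 library, whose peaks mostly did not recur in the other. Peaks were shifted along whole chromosomes, so the megabase blocks described below could give these results without sharing of single sites. The antibody was used in dBigH1ΔED cells alone, so what it recognised there cannot be checked against cells without that form.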

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

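The tests of X shares and of gained regions in this part were chosen only after the results were seen; the test within 5 score classes was set beforehand, and its repeat in 10 classes was added later. The lines differed in where their missing Rpb3 regions lay. Of arm regions in WT and dBigH1 libraries but in neither dBigH1ΔED library, 43 of 121 (35.5%) were on X, against 3 of 38 (7.89%) of those in WT and dBigH1ΔED but neither dBigH1 library (odds ratio 6.43, Fisher's exact p = 0.000833). X held 28.4% of arm regions missing in dBigH1ΔED relative to WT, against 19.7% of regions in all 4 libraries (odds ratio 1.62, Fisher's exact p = 0.000977, adjusted over 6 tests 0.00455). Regions missing in dBigH1 cells relative to WT showed no such excess, with 29 on X and 132 on the autosomal arms (Fisher's exact test, adjusted p = 0.50). These tests count regions, which are not independent replicates, and rest on 2 libraries per line.

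A weaker signal at X-linked peaks in general was argued against by comparing regions of like strength: within 5 equal classes of the score in WT replicate 1, loss was more frequent on X over the classes pooled (Mantel-Haenszel odds ratio 1.94, 1.41 to 2.68), as it did within 10 classes (2.03, 1.45 to 2.85). This rests on the 2 weakest classes, which held 63 and 13 of the 77 X losses (40.1% of X against 26.3% of autosomal regions, and 7.65% against 2.71%), while the middle class went the other way (0% against 1.07%), the next had no losses and the strongest had 1 on X and 1 elsewhere. Less stable calling on X in both directions cannot be told apart from the alternative, since X held 17.1% of regions gained relative to WT, against 19.7% (Fisher's exact p = 0.50), and 12.3% of those gained relative to dBigH1, against 19.8% (Fisher's exact p = 0.0327, adjusted 0.0546). Regions gained with dBigH1 relative to WT had 9 on X and 73 on the autosomal arms (Fisher's exact p = 0.0364, adjusted 0.0546), so all 3 sets of gains lay below the share in common regions without passing the adjusted threshold. A line-specific difference, such as fewer X copies or shallower sequencing of the dBigH1ΔED libraries, and an effect of the ΔED form itself both stay open, untested, because line and induced protein coincide.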

How the results depend on the processing

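Of 133 alternative values for 18 results, 111 were unchanged, meaning the same direction and side of the 0.05 threshold for differences (direction alone where 1 library stood for a group), a factor of at most 1.5 for counts of regions, and a shift of at most 1 SD between replicates for X shares within a group. Depth, unknown here, limits every comparison of list size. The permutation tests of 2 libraries against 2 and the test of the Jaccard index could not pass 0.05 under any setting. For these, unchanged means the same direction only. The replicate block, identical by construction, also counts among the 111. At a score of at least 100, the difference in peak number between dBigH1 and WT was -18.5 instead of 13, that between dBigH1ΔED and WT -149 instead of -45, that between dBigH1 and dBigH1ΔED 130.5 instead of 58, and X held 0.865% of H1 peaks. Restricted to the arms, X held 1.22% of H1 and 20.8% of WT Rpb3 peaks, as fewer peaks form the total. With equal numbers of best-scored peaks, each list was reduced to 96 peaks for the overlaps of the dBigH1 antibody. The excess with H1 was then -0.153 percentage points instead of 20.8, and that with Rpb3 -0.876 instead of -21.3. So short a reference leaves almost no overlap at shifted positions (0.153% and 0.876%), so these values do not show that either relation vanished. The H1 overlap with Rpb3 under this setting was -8.76 points instead of -17.7, with 1846 peaks per list and the same p. With 1 replicate left out, differences in peak number ranged from -126 to 152 (dBigH1 against WT), -102 to 12 (dBigH1ΔED against WT) and -81 to 197 (dBigH1 against dBigH1ΔED). Covered length of dBigH1 against WT ranged from -1.60 to 0.280 Mb, and specific regions from 405 to 528, 588 to 727 and 540 to 602 in the 3 comparisons. With 1 replicate left out, the overlap of dBigH1 antibody regions relative to shifts ranged from -22.1 to -13.8 points with Rpb3 and from 14.7 to 57.7 points with H1. Both passed the threshold when the peaks of either dBigH1 antibody list stood alone. The overlap with H1 also passed without H1 replicate 2, but not without H1 replicate 1. That with Rpb3 did not pass with either Rpb3 replicate left out. The cause of the other changes was not tested. A score of at least 100 left no reproducible dBigH1 antibody region, so those overlaps have no value. Arms alone for the overlaps was chosen after seeing the data.

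Replicate numbers are shared between groups but same-numbered libraries did not deviate together (correlations 0.0343, 0.0142 and -0.0314). With a replicate block the differences in peak number (13, -45 and 58), covered length (-0.659, -1.83 and 1.17 Mb) and specific regions (254, 418 and 377) are identical by construction, and its smallest p is 0.5.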

Other observations

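All tests in this part except the comparison with Rpb3 rank were chosen only after the result was seen. H1 peaks in dBigH1ΔED cells were grouped in megabase blocks that recurred in both libraries. On 2L, the interval from 14 to 18 Mb held 300 and 245 H1 peaks and 87 and 77 Rpb3 peaks, while 2 to 8 Mb held 3 and 3 H1 peaks and 265 and 266 Rpb3 peaks. On 3L, 2 to 6 Mb held 192 and 201 H1 peaks, and 8 to 16 Mb held 5 and 4. Peaks of the dBigH1 antibody numbered 23 and 16 against 0 and 0 in these 2L intervals, and 15 and 27 against 0 and 1 on 3L, but other H1-rich windows had none, such as 3R from 12 to 14 Mb with 47 and 55 H1 peaks. Over 46 bins of 2 Mb on the autosomal arms, H1 density in Rpb3-free sequence was lower where Rpb3 peaks were more numerous (Spearman's rho = -0.492, permutation p = 0.00066, adjusted 0.00099; Pearson's r = -0.615, permutation p = 1e-05, the smallest possible, and -0.528 without the 2 farthest bins). Peaks of the dBigH1 antibody were more numerous in bins with more H1 peaks (rho = 0.585, permutation p = 3e-05, adjusted 9e-05; r = 0.773, permutation p = 1e-05, and 0.670 without the 2 farthest bins), and none were called in 7 of the 28 bins with a mean of at least 20 H1 peaks and in 11 of the 18 bins with fewer. These were 2 of 3 relations computed over the bins, which are neighbours and not independent replicates.

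Few H1 peaks were called on X, at 20 and 19. Rpb3 peaks per Mb on X were 1.06 times the autosomal mean or more, so calling on X was not poor for peaks of every kind. H1 peaks scored lower, with medians of 92.9 and 87.9 against 639 and 692 for Rpb3 in the same cells. H1 peaks of score at least 100 were also few on X, at 7 and 7, against 157 and 144 at the autosomal arms' density. Weak Rpb3 peaks were not scarce on X, which held 20.3% of WT Rpb3 peaks and 20.1% at that score. The difference of dBigH1ΔED from WT went from -0.917 to -1.30 points. These values argue against poorer calling of weak peaks on X for Rpb3, and as the whole account of the H1 deficit. For H1 peaks below 100 it was not tested apart. Less polymerase-free sequence on X was argued against, since H1 peaks per Mb of Rpb3-free sequence on X were at most 0.0766 of the lowest autosomal arm. DNA copy number of the line cannot be told apart from a difference in H1. Across the 46 bins, H1 density tended to be higher where Rpb3 peaks ranked lower in their list (rho = 0.245, permutation p = 0.102). This did not pass the threshold, and copy number had been predicted to give the opposite direction. The test cannot decide, since the bins lay on the autosomal arms alone and bins dense in H1 also held fewer Rpb3 peaks (rho = -0.492). Whether inputs corrected the calls was not given. Less H1 on X in these cells is a candidate explanation, untested because DNA copy number was not measured here. Any part played by dBigH1ΔED is also untested, because H1 was not mapped in WT cells here.

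Most genotype-specific Rpb3 regions were weak, so calls near the threshold may account for many of them. Counting only regions in the better-ranked 50% of both lists, the genotype split kept 30 regions in dBigH1ΔED against WT and 37 in dBigH1 against dBigH1ΔED, against at most 3 for either other split, so threshold noise alone was argued against for those regions but not for the weaker majority. The 30 were 25 gained and 5 missing and the 37 were 16 specific to dBigH1 and 21 to dBigH1ΔED, the reverse of the balance over all regions, so they lend nothing to the excess of missing regions. For dBigH1 against WT it stays open, since 25 regions (15 gained, 10 missing) faced 12 in the crossed split. The 3 comparisons were first to be judged as 1 and were separated after their values were seen.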
